A study of Rhodococcus rhodochrous with 9 samples.

How the data were processed

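RNA of Rhodococcus EP4, given in the labels as Rhodococcus rhodochrous, was extracted with TRIzol from mid-log cultures grown in a mineral medium on 1.0 mM ethylphenol, propylguaiacol or succinate. Ribosomal RNA was removed with a kit for Gram-positive bacteria, libraries were made with a TruSeq kit, and all 9 were sequenced as read pairs on 1 lane of a HiSeq4000, per the labels. The labels do not state which ring isomer of ethylphenol or propylguaiacol was used. Ribosomal RNA depletion and shared lane apply to all groups alike.

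The submitters' processing notes name Trimmomatic 0.3.6, Bowtie2, Salmon and DESeq2, with no role or order. The genome build and the gene annotation are not given in the sources used here. The deposited values are a signal per locus tag, that is, normalized read counts, as read from the values themselves. They are not whole numbers, and the median ratio to the geometric mean of all libraries was the same in all 9 libraries, as median-of-ratios scaling gives. The divisor appears to vary slightly from tag to tag within a library as well, and how it was computed is not given in the sources used here. Such scaling takes the median tag as unchanged, so a carbon source that moved most tags in one direction would not show it. The libraries were also scaled to equal totals, which sets every library to the same sum and so cannot show such a change either. Under that scaling, tags that take much of a library's signal lower all its other tags.

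In most libraries low values lay near whole multiples of a step, which is what 1 read is worth in that library. Within a tolerance of 0.1 of a read, at least 95% of the low values were whole multiples in 2 of the 9 libraries, with shares from 22% in ethylphenol replicate 3 to 98.5% in propylguaiacol replicate 2. Whole reads were therefore not taken as recovered, and depths and ratios to counting noise, which take 1 divisor per library, are approximate. Sums and shares over tags are of normalized values, not of reads. Dividing each total by its step gave approximate depths of 21200000, 33700000 and 28900000 reads for ethylphenol replicates 1 to 3, 29700000, 22900000 and 29600000 for propylguaiacol and 20500000, 29600000 and 25000000 for succinate. The 20 highest tags took 29.6% to 30.8% of the signal on ethylphenol, 18.1% to 25.7% on propylguaiacol and 12.9% to 13.5% on succinate. Between 17 and 33 tags per library were listed at 0.

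A count model had been planned for the comparisons, with a test on log values as the fallback for files without counts. The fallback was used: limma 3.58.1 in R 4.3.3, with moderated statistics and a mean-variance trend, on log2(value + 1). Tags with a value of at least 1 in at least 3 libraries were tested, which kept 5108 of 5128. A single model with 1 mean per carbon source was fitted to all 9 libraries, so that the groups shared 1 estimate of the spread, with 6 residual degrees of freedom. A call is a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Fold changes are on the log2(value + 1) scale, which understates the change of tags with low values.

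Runs of neighbouring tags were counted where at least 5 consecutive tags were called in the same direction with an absolute log2 fold change of at least 1, and the number was set against 1000 random orders of the tags. The order came from the numbers in the locus tags, contig ends are not known, and an untested tag ends a run. The overlap of the responses was set beside independent lists and beside 100 simulations of unchanged groups that shared the succinate libraries. The share of signal in the region common to the longest runs of both comparisons with succinate, and the parts into which that region is divided, were chosen after the values were seen.

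The carbon source of each library, the model, the tests, most alternatives and the rule for named tags were set before the data were examined. For identifiers without a description the rule allowed 2 tags that rose and 2 that fell per comparison. They are those with the largest log2 fold change among called tags whose groups did not overlap and whose higher group reached 20 CPM, computed on the deposited values. Blocks are given by their first and last tag as positions, for the 3 longest runs of a comparison and any of equal length, and the longest lower run on ethylphenol was added after its values were seen. Gene lists by function had also been fixed beforehand, but the files pair no tag with a product and no annotation was used here, so none of these lists could be tested.

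On simulated data with the spread of the 9 libraries and 200 of 5108 tags changed, the fit for ethylphenol against succinate recovered 17% of 2-fold and 44% of 4-fold changes, and 3.17% of its 63 calls were false. With the spread of the libraries other than propylguaiacol replicate 2 it recovered 94% and 98%, and 6.34% of 205 calls were false. These simulations gave all libraries the same pooled spread, whereas ethylphenol and succinate libraries spread less, so the recovered shares do not describe the real fit. In the data, ethylphenol against succinate had 295 calls from all 9 libraries. It had 2974 without propylguaiacol replicate 2 and 2729 from its own 6 libraries. The number from all 9 libraries is thus held down by the spread that this replicate adds to the shared estimate. For the comparisons with propylguaiacol the shared estimate errs the other way: in 100 simulations with no tag changed and each group at its own spread, the same fit called 88.7 tags on average for propylguaiacol against succinate, 84.8 for ethylphenol against propylguaiacol and 0.01 for ethylphenol against succinate. Adjusted p-values in the comparisons with propylguaiacol are thus too small for part of the tags.

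Replicates were compared before they were averaged. For tags at 1000 to 10000, propylguaiacol replicates 1 and 3 differed with about 2.28 times the variance of counting, against 6.36 to 53.3 times for pairs within ethylphenol or succinate. Their difference was above that estimate of counting noise, but divisors that vary between tags could account for the excess, so it does not establish separate libraries. They were kept apart as labelled, so n = 3 for propylguaiacol counts labelled libraries, and averaging them was run as an alternative. Alternatives were other pseudocounts, other filters on low values, other limits for runs, a replicate term, fits on 6 libraries, a test against a 2-fold change, equal totals, library weights, and each library left out in turn.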

Results

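RNA from mid-log cultures of Rhodococcus EP4, an actinobacterium of a genus known for growth on aromatic compounds, was sequenced after growth on 1 of 3 carbon sources, each supplied at 1.0 mM. Ethylphenol and propylguaiacol are alkylated phenols of the kind released when lignin is broken down, and succinate is an intermediate of the tricarboxylic acid cycle. There were 3 libraries per carbon source, 9 in all, and each library had a normalized read count for 5128 locus tags, the systematic identifiers of annotated genes. The totals of the normalized counts were 21975870, 21179114 and 21698676 for succinate replicates 1 to 3, 27521864, 26425565 and 28126521 for ethylphenol, and 25410026, 47206219 and 25395095 for propylguaiacol. Approximate depths read from the smallest steps between low values lay between 20500000 and 33700000 reads per library. The files pair no locus tag with a gene name or product, so the genes are described by tag, by level and by their place in the tag order.

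The libraries separated by carbon source, apart from propylguaiacol replicate 2. Across the locus tags, Spearman's rank correlation lay between 0.991 and 0.993 within succinate and between 0.995 and 0.997 within ethylphenol. Propylguaiacol replicates 1 and 3 correlated at 0.999, whereas replicate 2 correlated with them at 0.721 and 0.717. Replicate 2 correlated higher with the ethylphenol libraries, at 0.769 to 0.780, than with its own group, and at 0.689 to 0.700 with succinate. All other pairs of libraries from different groups lay between 0.922 and 0.943. Locus tags are not independent replicates, so no p-value was attached to these correlations. The labels do not say whether the replicates came from separate cultures, and the p-values therefore measure the spread between these libraries, which may be technical in part.

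**Figure D1:**
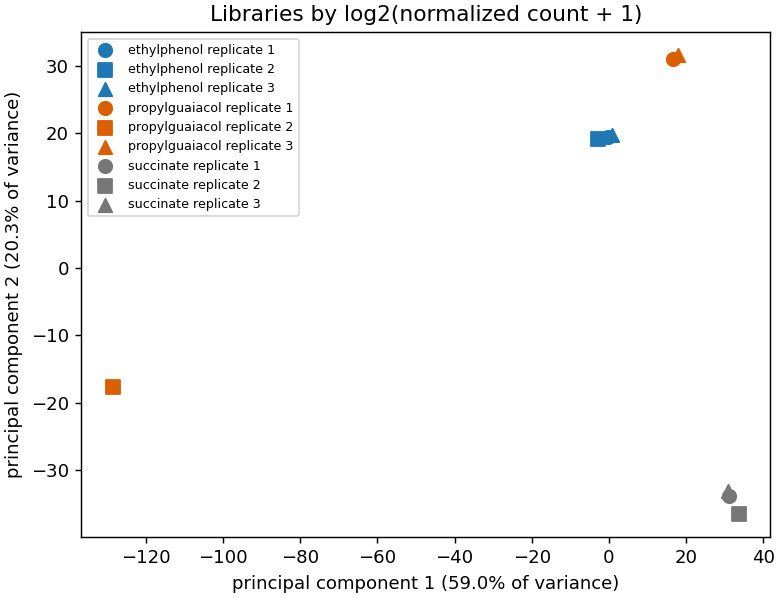
Principal components 1 (59.0% of the variance) and 2 (20.3%) of log2(normalized count + 1) over the 5108 tested locus tags, with 1 point per library, colour for the carbon source and shape for the replicate number. Propylguaiacol replicate 2 lies at -128.61 on component 1, and the other 8 libraries lie between -2.88 and 33.79.

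The first comparison asked which genes differed in transcript level between growth on ethylphenol and growth on succinate. The largest difference lay in a block of 20 neighbouring locus tags, C6369_RS23655 to C6369_RS23750, which were all higher on ethylphenol, with a median log2 fold change of 10.03. A further block of 11 tags, C6369_RS24900 to C6369_RS24950, summed to 69032 ± 3271 normalized counts on ethylphenol and 10218 ± 989 on succinate (SD, n = 3 each; median log2 fold change 2.55). A block of 9 tags, C6369_RS17975 to C6369_RS18015, summed to 433287 ± 32583 on ethylphenol and 8406 ± 2090 on succinate (SD, n = 3 each; median 3.34). The longest block that was lower on ethylphenol held 6 tags, C6369_RS21440 to C6369_RS21465, which summed to 273 ± 27.3 against 3930 ± 714 (SD, n = 3 each; median -3.70).

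Among single tags, C6369_RS23715 rose from 401 ± 48.0 normalized counts on succinate to 1201856 ± 55778 on ethylphenol (SD, n = 3 each), a log2 fold change of 11.55 (SE 0.571, limma adjusted p = 1.33e-05). C6369_RS23670 rose from 326 ± 51.8 to 700280 ± 31380, a log2 fold change of 11.08 (SE 0.209, limma adjusted p = 1.99e-08). In the opposite direction, C6369_RS13280 stood at 118 ± 6.22 on ethylphenol against 93457 ± 21293 on succinate, a log2 fold change of -9.60 (SE 0.242, limma adjusted p = 1.32e-07). C6369_RS09950 stood at 1351 ± 88.2 against 107508 ± 21198, a log2 fold change of -6.30 (SE 0.267, limma adjusted p = 4.96e-06). All 3 ethylphenol libraries lay on the stated side of all 3 succinate libraries for each of these 4 tags, as the rule for named tags required.

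Of 5108 tested tags, 178 were higher and 117 lower on ethylphenol at a limma adjusted p under 0.05, and 161 and 100 of these changed at least 2-fold. Runs of at least 5 neighbouring tags called in one direction and changed at least 2-fold numbered 6 and held 56 tags. No random order of the tags among 1000 gave more than 1 such run (one-sided permutation p = 0.001, the smallest these orders can give). Without propylguaiacol replicate 2, whose spread enters the shared error estimate, the calls numbered 1475 higher and 1499 lower and the runs 21, while leaving out any 1 ethylphenol or succinate library gave 125 to 149 calls and 2 or 3 runs. In those 6 fits at least 18, 7 and 4 tags of the blocks from C6369_RS23655, C6369_RS24900 and C6369_RS17975 were still called, and 0 tags of the lower block from C6369_RS21440. With the libraries scaled to equal totals, which moved the median log2 fold change of all tags from -0.02 to -0.36, 79 tags were higher and 95 lower. That shift follows from the larger totals of the ethylphenol libraries and does not show whether most tags moved.

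**Figure D2:**
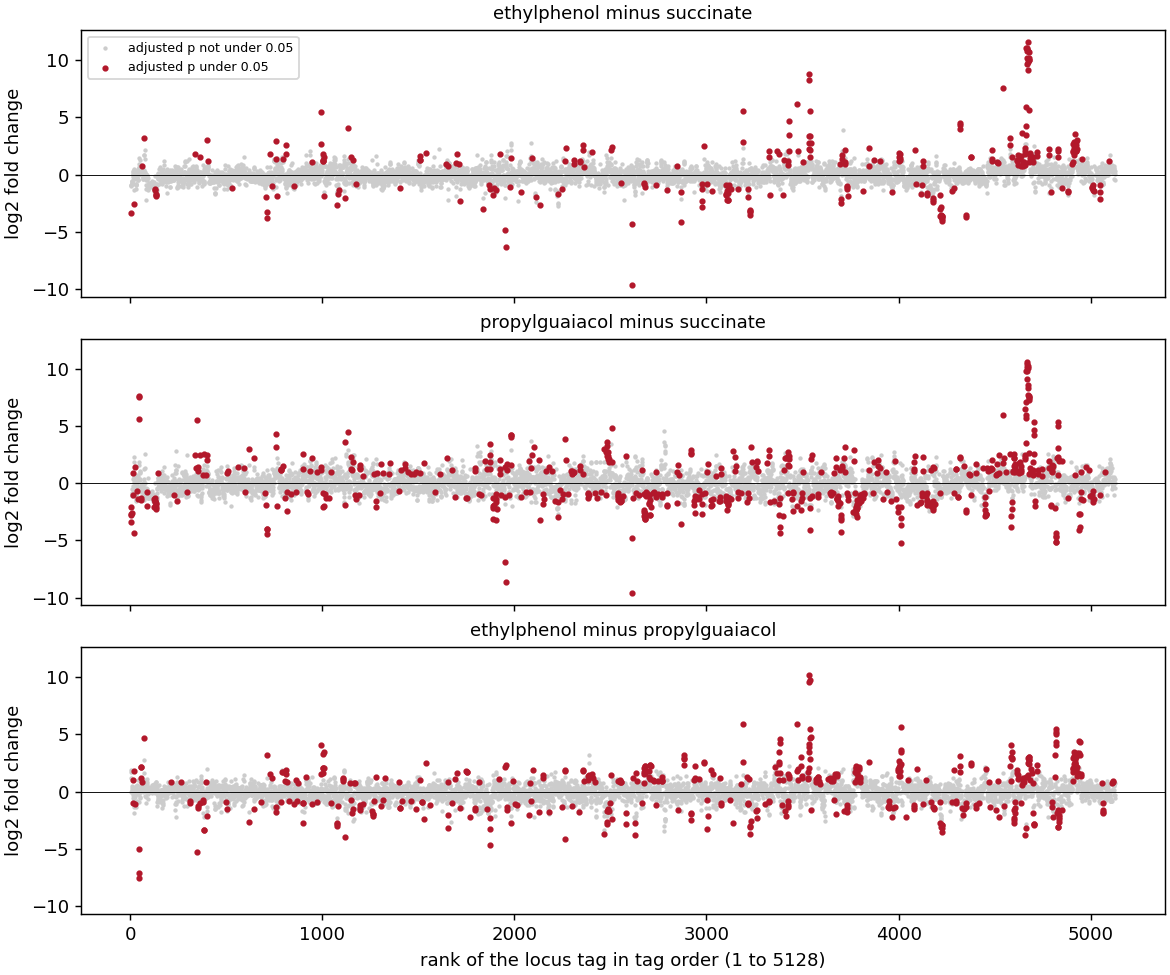
Log2 fold change on log2(normalized count + 1) for each tested locus tag, in tag order, for ethylphenol minus succinate (top), propylguaiacol minus succinate (middle) and ethylphenol minus propylguaiacol (bottom). Red points have a limma adjusted p under 0.05 (295, 609 and 486 tags), and the cluster of the highest red points at the right of the top and middle panels is the block around C6369_RS23670.

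The second comparison set propylguaiacol against succinate. A block of 24 neighbouring tags, C6369_RS23630 to C6369_RS23745, was higher on propylguaiacol in its entirety, with a median log2 fold change of 7.59, and it contained 19 of the 20 tags of the longest block seen on ethylphenol. A block of 12 tags, C6369_RS19195 to C6369_RS19250, was lower on propylguaiacol and summed to 2601 ± 637 normalized counts against 9984 ± 598 on succinate (SD, n = 3 each; median log2 fold change -2.18). The next blocks in length held 8 tags each. C6369_RS12595 to C6369_RS12630 was higher, at 4549 ± 2262 against 650 ± 47.1 (SD, n = 3 each; median 2.73), with propylguaiacol replicate 2 at 1937 and the other 2 replicates at 5847 and 5863. C6369_RS13605 to C6369_RS13640 was lower, at 901 ± 211 against 5714 ± 593 (median -2.79), and so was C6369_RS22590 to C6369_RS22625, at 8174 ± 2889 against 26804 ± 1544 (median -2.71; SD, n = 3 each). In the latter block propylguaiacol replicate 2 summed to 4839 and the other 2 replicates to 9832 and 9852, and the median was -1.96 without replicate 2.

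The single tags with the largest rise were C6369_RS23685 and C6369_RS23690. C6369_RS23685 went from 112 ± 15.3 normalized counts on succinate to 175722 ± 17932 on propylguaiacol (SD, n = 3 each), a log2 fold change of 10.60 (SE 0.194, limma adjusted p = 2.39e-08). C6369_RS23690 went from 97.4 ± 5.97 to 133461 ± 13282, a log2 fold change of 10.40 (SE 0.177, limma adjusted p = 2.32e-08). The tags with the largest fall were those of the ethylphenol comparison. C6369_RS13280 stood at 120 ± 28.7 on propylguaiacol (log2 fold change -9.60, SE 0.242, limma adjusted p = 1.48e-07) and C6369_RS09950 at 278 ± 77.2 (log2 fold change -8.61, SE 0.267, limma adjusted p = 5.79e-07). All 3 propylguaiacol libraries, replicate 2 included, lay on the stated side of all 3 succinate libraries for these 4 tags, which the rule for named tags required.

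In total 285 tags were higher and 324 lower on propylguaiacol (limma adjusted p under 0.05), and 231 and 256 of them changed at least 2-fold. The shared error estimate is too small for propylguaiacol, whose libraries spread most: 100 simulations of unchanged groups, each with its own spread, gave 88.7 calls on average (highest 153) in this comparison, so a part of the 609 calls can be false beyond the stated rate. A fit on only the 6 libraries compared gave 200 calls. Runs of at least 5 neighbouring tags numbered 11, with 91 tags, 5 of the runs higher and 6 lower, against at most 1 in 1000 random orders (one-sided permutation p = 0.001, the smallest possible). Without propylguaiacol replicate 2 the calls numbered 1190 higher and 1399 lower and the runs 35. That fit rests on propylguaiacol replicates 1 and 3, which nearly coincide and may not be separate cultures. Replicate 2 lay on the called side of succinate in 1603 of these 2589 calls (61.9%). Leaving out succinate replicate 1, 2 or 3 gave 321, 287 and 301 calls and 4, 4 and 5 runs, leaving out ethylphenol replicate 1 or 3 gave 386 and 390 calls. Without any 1 of the 9 libraries, all tags of the blocks from C6369_RS23630 and C6369_RS13605 kept their call, at least 9 of the 12 from C6369_RS19195 and at least 4 of the 8 from C6369_RS12595 did, and the block from C6369_RS22590 kept 1, 1 and 2 of 8 without succinate replicate 1, 2 and 3. With equal totals, which moved the median log2 fold change of all tags from 0.00 to -0.52, 125 tags were higher and 486 lower. That shift follows from the totals as well, among them the 47206219 of propylguaiacol replicate 2.

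The longest blocks of the comparisons with succinate had 19 tags in common, C6369_RS23655 to C6369_RS23745, referred to as the shared region. This region took 26.1% ± 0.712 of all normalized counts on ethylphenol, 10.8% ± 1.40 on propylguaiacol and 0.0521% ± 0.00687 on succinate (SD, n = 3 each). The region was chosen for being higher on both aromatic compounds than on succinate, so its separation from succinate is not tested by these shares. Between the aromatic compounds the libraries did not overlap, with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. Log2 fold changes over the 19 tags ran from 3.45 to 11.55 on ethylphenol (median 10.08) and from 2.62 to 10.60 on propylguaiacol (median 8.30).

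**Figure D3:**
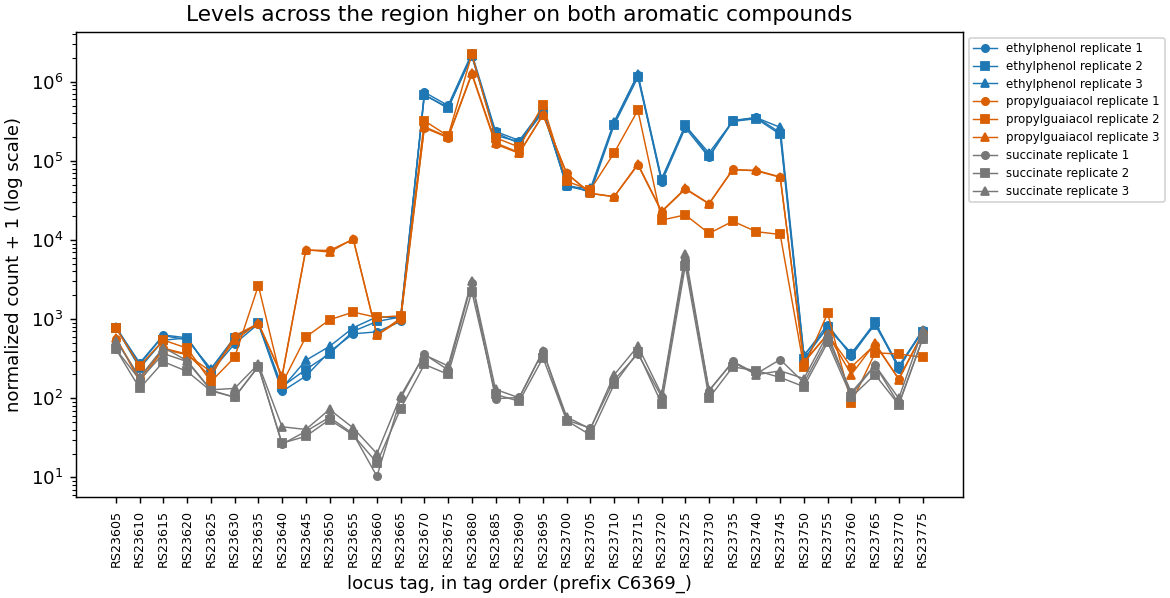
Normalized count + 1 on a log scale for the locus tags around the shared region, in tag order, with 1 line per library, colour for the carbon source and marker for the replicate. From C6369_RS23670 to C6369_RS23745 the 6 libraries from aromatic compounds lie above the 3 succinate libraries, ethylphenol lies above propylguaiacol from C6369_RS23710 to C6369_RS23745, and propylguaiacol replicates 1 and 3 lie highest from C6369_RS23645 to C6369_RS23655.

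Altogether 85 tags were higher and 72 lower on both aromatic compounds than on succinate (limma adjusted p under 0.05). Lists of these sizes drawn independently would share 9.93 and 7.42 tags. In 100 simulations of unchanged groups against the same succinate libraries 0 tags were shared, but the ethylphenol comparison averaged 0.01 calls there, so this 0 carries no information on the shared controls. At an unadjusted p under 0.05, 221 tags were higher and 238 lower on both compounds, against 9.88 and 9.59 on average in the simulations (highest 17 each) and 59.3 and 58.3 for independent lists. The simulated groups held no changed tags, whereas 879 and 1369 tags passed that limma p in the data. The simulated averages therefore do not show how much the shared controls add to 221 and 238. The log2 fold changes of the 2 comparisons had a covariance over tags of 0.748, against 0.0211 in the simulations (a difference of 0.727), and a Pearson correlation of 0.629 against 0.155. The 19 tags of the shared region, with median log2 fold changes of 10.08 and 8.30, weigh heavily in both measures. Neither measure was computed without them, so they do not describe the tags at large. The same succinate libraries served both comparisons, as they did in the simulations, and could not be divided between them. Of the 85 tags higher on both, 18 were higher on ethylphenol than on propylguaiacol, 14 were lower and 53 had no call between the compounds. Of the 72 lower on both, the numbers were 8, 4 and 60. The overlap of 157 tags became 1224 without propylguaiacol replicate 2, where both comparisons had more calls, and no expected overlap was computed for that fit. The fold changes agreed less there: the covariance was 0.555, the Pearson correlation 0.520. The share of tags with the same sign fell from 71.2% to 61.6%. The simulations, which kept that replicate, gave a share of 59.1% on average (highest 61.1%). The overlap was 70 to 79 without any 1 ethylphenol or succinate library, and with equal totals it was 36 higher and 65 lower.

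The third comparison set the aromatic compounds against each other at the same concentration and growth phase. Propylguaiacol carries a methoxy group next to the hydroxyl and a propyl chain, whereas ethylphenol carries an ethyl chain. Within the shared region, the 8 tags from C6369_RS23710 to C6369_RS23745 were higher on ethylphenol, at a sum of 2853978 ± 99016 normalized counts against 509177 ± 126098 on propylguaiacol (SD, n = 3 each), with log2 differences of 1.43 to 3.07 and limma adjusted p from 0.00167 to 0.0321. Their median log2 difference was 2.74 with all libraries and 2.13 without propylguaiacol replicate 2. For the neighbouring 8 tags, C6369_RS23670 to C6369_RS23705, the sums were 4275695 ± 174430 and 2902664 ± 685781. Here 2 tags were called higher on ethylphenol, and for the 6 without a call the 95% intervals of the log2 difference together spanned -0.83 to 1.18, so differences within those bounds are not excluded. Without propylguaiacol replicate 2, 5 of these 8 tags were called higher on ethylphenol and 1 higher on propylguaiacol.

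Outside that region, a block of 11 tags, C6369_RS17955 to C6369_RS18005, summed to 386453 ± 29343 on ethylphenol and 1324 ± 633 on propylguaiacol, with 3766 ± 1772 on succinate (SD, n = 3 each; median log2 difference 3.45). The 10 tags from C6369_RS24900 to C6369_RS24945 were higher on ethylphenol than on propylguaiacol (median 2.48), and on propylguaiacol 1 of the 10 was called higher than on succinate. The 8 tags from C6369_RS13605 to C6369_RS13640, which were lower on propylguaiacol than on succinate, were also higher on ethylphenol than on propylguaiacol (median 1.93).

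C6369_RS17995 had 262147 ± 19639 normalized counts on ethylphenol and 244 ± 112 on propylguaiacol (SD, n = 3 each), a log2 difference of 10.17 (95% interval 8.91 to 11.42, SE 0.542, limma adjusted p = 4.91e-05). C6369_RS18000 had 48886 ± 7366 and 57.9 ± 16.1, a log2 difference of 9.72 (95% interval 8.49 to 10.95, SE 0.531, limma adjusted p = 4.91e-05). The tags with the largest difference in favour of propylguaiacol were C6369_RS00230 and C6369_RS00225. C6369_RS00230 stood at 42.9 ± 26.1 on ethylphenol and at 3078, 37639 and 3163 in propylguaiacol replicates 1 to 3, a log2 difference of -7.52 (SE 0.935, limma adjusted p = 0.00298) that was -8.13, -6.32 and -8.11 without replicate 1, 2 and 3 in turn. C6369_RS00225 stood at 485, 113 and 100 in ethylphenol replicates 1 to 3 and at 10591, 128103 and 10776 on propylguaiacol, a log2 difference of -7.11 (SE 1.01, limma adjusted p = 0.00511). It was -7.83 without ethylphenol replicate 1 and -7.71, -5.91 and -7.70 without propylguaiacol replicate 1, 2 and 3.

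Between the aromatic compounds 280 tags were higher on ethylphenol and 206 higher on propylguaiacol (limma adjusted p under 0.05), and 227 and 166 of these differed at least 2-fold. The same simulations of unchanged groups gave 84.8 calls on average (highest 134) in this comparison, and a fit on only the 6 libraries compared gave 157 calls. Runs of at least 5 neighbouring tags numbered 10, 9 of them higher on ethylphenol, against 0 in 1000 random orders (one-sided permutation p = 0.001, the smallest possible). Without propylguaiacol replicate 2, which leaves replicates 1 and 3, possibly not separate cultures, the calls numbered 1490 and 1404 and the runs 44. Without propylguaiacol replicate 1 or 3 there were 250 and 270 calls, and without ethylphenol replicate 1, 2 or 3 there were 166, 187 and 175 calls and 3 runs each. In each of the latter fits 3 of the 8 tags from C6369_RS23710 to C6369_RS23745 were still called, and over all 9 fits with 1 library left out at least 7, 9 and 6 tags of the blocks from C6369_RS17955, C6369_RS24900 and C6369_RS13605 were. With equal totals, which moved the median log2 difference of all tags from 0.00 to 0.19, 226 tags were higher on ethylphenol and 86 on propylguaiacol, and 5 of the 8 tags from C6369_RS23710 were called. Here too the shift of the median follows from the totals.

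**Figure D4:**
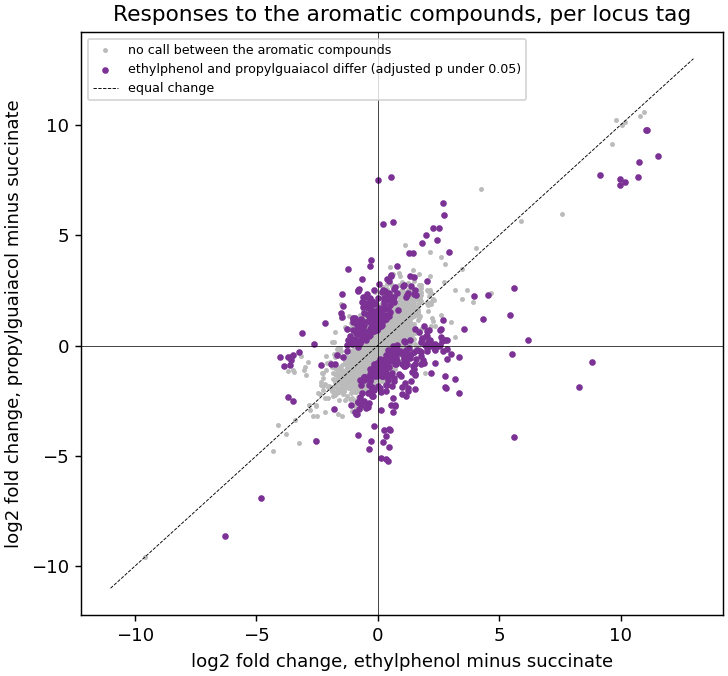
Log2 fold change on propylguaiacol against log2 fold change on ethylphenol, both minus succinate on log2(normalized count + 1), with 1 point per tested locus tag. Purple points are the 486 tags called between the aromatic compounds at a limma adjusted p under 0.05, the dashed line marks equal change, and the points at the upper right belong mostly to the shared region.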

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

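A filter at 50, tests against a 2-fold change, equal totals, library weights, the average of propylguaiacol replicates 1 and 3, and the fit without a library of the group not compared were chosen only after the data were seen, and so were the settings for the overlap and the runs other than limits, the replicate term and the left-out libraries. Each of the 12 pairs of named tag and comparison kept its direction and call in all 237 alternative values. With any 1 library of its group left out, the mean share of signal in the shared region was 0.0487% to 0.0555% on succinate, 25.8% to 26.5% on ethylphenol and 10.4% to 11.6% on propylguaiacol. Pseudocounts of 0.1 and 10, no filter, a filter at 50 and leaving out the 20 highest tags kept every number of calls, runs and shared tags within 1.5 times. For ethylphenol against succinate, propylguaiacol against succinate and ethylphenol against propylguaiacol in turn, the 295, 609 and 486 calls became 2729, 200 and 157 with only the 6 libraries compared, 63, 125 and 70 against a 2-fold change, and 3086, 3033 and 3880 with library weights, which gave propylguaiacol replicate 2 a weight of 0.00745. Equal totals gave 174, 611 and 312 calls, and averaging propylguaiacol replicates 1 and 3 gave 260 for ethylphenol against propylguaiacol. With 1 library left out, calls ranged from 125 to 2974, 287 to 2589 and 166 to 2894, the highest each time without propylguaiacol replicate 2. The 6, 11 and 10 runs became 20, 40 and 41 at a minimum length of 3, 3, 5 and 4 at a length of 8, 21, 3 and 3 with 6 libraries, 2, 3 and 2 against a 2-fold change, and 21, 32 and 45 with library weights. A limit of 4-fold (log2 of 2) gave 7 runs for propylguaiacol against succinate and 5 for ethylphenol against propylguaiacol, and equal totals gave 18 for propylguaiacol against succinate. With 1 library left out, runs ranged from 2 to 21, 4 to 35 and 3 to 44. The 157 shared tags became 38 against a 2-fold change, 101 with equal totals and 1370 with library weights, and ranged from 70 to 1224 with 1 library left out. By construction a longer minimum length lowers and a shorter one raises the number of runs, and the test against a 2-fold change lowers the calls and shared tags. The settings that removed or down-weighted propylguaiacol replicate 2 in a comparison's fit gave it more calls. For the other settings the cause was not tested. Whether the depth of 20500000 to 33700000 reads per library limited the calls was not tested. For tags at 1000 to 10000, propylguaiacol replicate 2 differed from replicates 1 and 3 with about 1963 and 1981 times the variance of counting. Between replicates 1 and 3 the ratio was 2.28.

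The replicate numbers did not pair the libraries: the deviations of same-numbered libraries correlated at -0.09 to 0.28, 4 of 9 such pairs lay over 0.1, and 5 of 9 libraries correlated best with one of their own number. With the replicate number as a block, the calls were 168, 384 and 312, the runs 3, 6 and 8, and the shared tags 85.

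The planned count models, their scaling factors and filters, and the gene list tests were not run, since the files hold neither counts nor products.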

Other observations

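The tests of explanations and the splits in this part were chosen only after the results were seen, as were equal totals, fits without a library of a group not compared, and the blocks and tags described, whereas the calls and runs of each comparison and the fits without 1 of its own libraries were planned.

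In 8 tags the responses to the aromatic compounds went in opposite directions from succinate, each with a limma adjusted p under 0.05 in both comparisons and between the compounds. Of these, 7 were higher on ethylphenol and lower on propylguaiacol, 3 of them within C6369_RS05095 to C6369_RS05115 and 3 within C6369_RS17975 to C6369_RS18015. The remaining tag, C6369_RS09540, was lower on ethylphenol (log2 fold change -1.22) and higher on propylguaiacol (3.45). Leaving out 1 library other than propylguaiacol replicate 2 kept 2 to 6 of the 8, the fewest without ethylphenol replicate 1 or 3 or succinate replicate 2. Without propylguaiacol replicate 2, where calls are many, all 8 were kept and the number of such tags was 477. The number of tags with opposite responses thus depends on that library, and 8 is not a limit. C6369_RS18000 and C6369_RS18015 were kept in each of the 9 fits. A block of 5 tags, C6369_RS24430 to C6369_RS24450, summed to 201012 ± 26650 normalized counts on succinate, 219608 ± 18996 on ethylphenol and 7354 ± 1730 on propylguaiacol (SD, n = 3 each). All 5 were called lower on propylguaiacol than on either other carbon source (median log2 fold change -4.68 against succinate), and they remained called without any 1 library and with equal totals. No tag of this block was called between ethylphenol and succinate.

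A block of 5 tags not far along the tag order from the shared region, C6369_RS23855 to C6369_RS23875, was higher on propylguaiacol than on succinate (median log2 fold change 4.17, and 4.83 without propylguaiacol replicate 2). It summed to 1807 ± 227 normalized counts on succinate, 6611 ± 1285 on ethylphenol and, on propylguaiacol, 69292, 13348 and 67818 in replicates 1 to 3. At the left edge of the shared region, C6369_RS23645 to C6369_RS23655 showed the same order of replicates, with 25067, 2798 and 24874 on propylguaiacol against 1351 ± 159 on ethylphenol (SD, n = 3). Of these 3 tags, whose limma adjusted p between the aromatic compounds ran from 0.0293 to 0.0541, 2 were called higher on propylguaiacol, 3 without propylguaiacol replicate 2 (log2 differences -4.99 to -3.85), and 0 without any 1 of the other 8 libraries or with equal totals.

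Propylguaiacol replicate 2 lay more than 2-fold away from the mean of replicates 1 and 3 in 3149 of 5108 tags. A label swapped within the series is argued against by its rank correlations with the other groups, which reached 0.780 where the lowest within ethylphenol or succinate was 0.991. Its approximate depth of 22900000 reads lay inside the range of the other libraries, 20500000 to 33700000, and a mixture of RNA from the other cultures cannot place 42.9% of its tags more than 2-fold outside the range of the other 8 libraries (49.9% at equal totals). A culture in another state at harvest, or a fault in making or labelling the library with RNA from outside the series, may account for it. By rank correlation replicate 2 was closer to the ethylphenol libraries (0.769 to 0.780) than to propylguaiacol replicates 1 and 3 (0.721 and 0.717). It also shared some features of its group, which RNA from outside the series would need to show as well. The block from C6369_RS24430 summed to 5464 in it and to 8859 and 7739 in replicates 1 and 3, against 201012 on succinate. Of 881 tags called and changed at least 2-fold from succinate without it, it lay on the same side in 600 (68.1%). No such share was computed for the ethylphenol libraries, so this one is not shown to be particular to propylguaiacol. No biological explanation was tested, since the labels name none.

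Propylguaiacol replicates 1 and 3 differed by a median of 0.0419 (log2, tags at 1000 to 10000), where pairs within ethylphenol or succinate differed by 0.0789 to 0.203. With 1 divisor per library the variance of their difference was 2.28 times counting noise, an excess SD of 0.0471 in log2. A single library deposited as separate read sets stays open, because divisors that vary between tags could add up to 0.107 to a pair, judged from the low tags of the library where they varied most, although they varied less in these 2 libraries (SD 0.0110 and 0.0118). The pair could also be libraries from 1 culture or RNA sample, which cannot be told apart from close cultures because the labels do not describe how replicates were made.

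The tags of the shared region differed between the aromatic compounds by unequal amounts, with log2 differences from -0.41 to 3.07 in 18 tags and -2.83, without a call, in the edge tag C6369_RS23655. A single factor for the whole region would leave the ratio of its last 9 to its first 9 tags alike within a library, but the log2 of that ratio was -0.53 ± 0.08 on ethylphenol and -2.35 ± 0.02 on propylguaiacol (SD, n = 3 each), a difference of 1.82 where the widest range within either group was 0.15. Propylguaiacol replicate 2 alone does not make the difference, which was 1.81 without it. The SD of 0.02 describes sums over tags, though, and not a common profile of the propylguaiacol libraries. C6369_RS23715 stood at 435994 in replicate 2 and at 89000 and 91201 in replicates 1 and 3. The sums of the 8 tags from C6369_RS23710 were 654758 in replicate 2 and 434068 and 438706 in the others. Of the 8 tags from C6369_RS23710 to C6369_RS23745, all called higher on ethylphenol, 3 were still called without any 1 ethylphenol library. A candidate explanation is that the region holds more than 1 transcription unit, with different responses to the compounds, which the difference of 1.82 allows and no test here addressed.

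Splits of the 6 libraries of a comparison into other groups of 3 number 10 with the real one, 1 of which gave as many calls or runs, and 10 are too few for a share under 0.05. The real splits gave 295, 609 and 486 calls and 6, 11 and 10 runs for ethylphenol against succinate, propylguaiacol against succinate and ethylphenol against propylguaiacol, and the highest other split gave 0 calls and 0 runs in limma. At an unadjusted p under 0.05 those other splits had at most 38, 455 and 728 tags. For the tags called in the same direction on both aromatic compounds, 1 of 100 splits of the 9 libraries, the real one, gave as many (157, highest other 80), but 97 of the other 99 gave 0 because mixed groups have a large spread. That number depends on the small spread within the real groups as well as on the overlap, so its rank cannot exclude chance assignment for the overlap itself. At an unadjusted p under 0.05 in limma the real split shared 459 tags and the highest other 395, and the spread enters there too. Chance assignment is not excluded for the overlap by fold alone, where 410 tags changed at least 2-fold in the same direction on both compounds. Of all 840 splits 220 gave as many, 212 of them with propylguaiacol replicate 2 in the group that stands for succinate. The rest of the 220, the real split included, were among the 560 splits with that replicate outside that group.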
